A study of Caenorhabditis elegans with 2 samples.

How the data were processed

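The data are peak lists from ChIP-seq against GFP in whole young adult worms of the strain with GFP-tagged F37B4.10, 61 h old per the labels, from 1 group of 2 biological replicates. Chromatin was sonicated to 200 to 800 bp per the labels. The lists use the ce11 assembly per the README files deposited with each sample, and each was derived there from filtered alignments and a control library. The aligner, the peak caller and the number of reads are not given in the sources used here, so the depth of each sample is unknown. The control library, alignments and coverage tracks were not analysed here.

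The authors deposited 2 kinds of list, without headers. Ranked lists hold candidate peaks with an irreproducible discovery rate (IDR), a measure of how consistently a peak ranks between 2 inputs, as −log10 values written by the authors, and hold 58046 peaks for replicate 1, 63045 for replicate 2, and 115634 and 117865 for both replicates together. Thresholded lists hold 81, 99, 843 (named conservative by the authors) and 947 peaks respectively, each with an IDR of at most 0.01. Lists of single replicates were made from 1 replicate's alignment, and joint lists from both. Per the README files deposited with each sample, thresholded lists were also derived from a further file whose content is not stated there. The signal column holds the authors' own value per peak, whose scale is not stated, so it was used to rank and describe peaks within a list, and its comparison between the replicates' lists assumes 1 scale. Of the 843 peaks, 835 are 276 bp wide, 8 are narrower, and 836 summits are the middle of the interval. In the joint ranked lists, 14 columns of values per input that name no sample were not used, except the 2 inputs' signals, which served for their correlation only.

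The conservative list was the main list. Positions were compared with the WBcel235 assembly, the same sequence as ce11 (all 6 nuclear chromosome lengths matched), and Ensembl release 115 gene annotation with 19973 protein-coding genes and 29314 distinct starts. A promoter ran from 1000 bp upstream to 200 bp downstream of any protein-coding start. Summits were assigned to promoter, 5' UTR, CDS, 3' UTR, other exon, intron or intergenic sequence, in that order. Promoter share, classes and noncoding genes within 200 bp were tested 2-sided against 10000 uniform placements of the same number of positions per chromosome. Overlap of lists, by any base, was tested one-sided with 10000 placements. Gene lists (33 of protein-coding genes and 1 of microRNA genes) and sequences used 2-sided Fisher's exact tests, chromosomes exact binomial tests, and signal differences 100000 permutations, with Benjamini-Hochberg adjustment within each family. Genes sharing a peak were counted separately. Members of each list were matched by patterns in gene symbols alone, so a list's name need not describe the function of every member. MicroRNA genes were matched after removing the species prefix of the annotation's symbols and compared with all 46890 annotated genes. Sequences were counted within 50 bp of a summit, with flanks centred 300 bp to each side as controls. Fisher's exact tests treated summits and flanks of the same peak as independent windows, which ignores their pairing. Intervals are exact (Clopper-Pearson) at 95%.

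Before the data were examined, the samples' groups, tests, gene lists, sites, most alternatives and the rule for named genes were fixed. The rule takes the 25 peaks of highest signal with the genes whose promoters hold them or else the nearest start, F37B4.10 and unc-119, up to 4 members of each list that passed or had at least 3 members at peaks, up to 3 members of each noncoding class that passed, the 10 sequences of 6 bases with the smallest p, and each site that passed. Other genes named are members of small groups, chosen after their values were seen. Alternatives were the authors' other joint list, the 421 peaks of highest signal, each replicate's own list, other promoter windows, distances and overlaps, circular shifts, the nearest gene, genes with a symbol only, shuffled sequence, and leaving out the transgene loci. Placements and windows matched on chromosome and GC content (bins of 3 bases in 101 bp; 2000 placements for gene lists), 1 flank per peak, and subsets without soft-masked summits or without peaks near small RNA genes were added after seeing the data.

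Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on 20 simulated sets of 843 random peaks, where promoters, noncoding classes, gene lists and 6-base sequences passed in 0 sets and the signal difference in 2, and on 20 sets with planted effects on promoters, tRNA genes, ribosomal protein genes, a 6-base sequence, signal, a locus and list overlap, all of which were recovered in 20 of 20. The planted signal shift was 20, against a difference of 2.33 in the data, so its recovery does not show power for the latter. Simulated sets also used fewer placements and permutations than the data. On 20 GC-rich simulated sets, GC-matched placements gave p under 0.05 for promoters in 2 and for coding sequence in 3.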

Results

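Chromatin immunoprecipitation followed by sequencing (ChIP-seq) mapped DNA that came down with tagged F37B4.10 protein in whole Caenorhabditis elegans young adults aged 61 h. The worms, of strain OP374, carried an integrated transgene that expresses F37B4.10 with a GFP tag, and an antibody against GFP pulled down the tagged protein with its DNA. The design holds 1 group of 2 biological replicates, so it asks where in the genome the tagged protein was enriched and how alike the replicates were. The description rests on 843 peaks, the authors' conservative list of peaks found reproducibly across both replicates. Their signal, the authors' value per peak on a scale not stated, had a median of 75.3 and a maximum of 321. Read depth is unknown, and intervals on shares of peaks cover counting error only. Coordinates refer to ce11.

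The 3 strongest peaks lay at rpa-2, at rpl-3 and at a pair of small nucleolar RNA genes. The highest signal of the list, 321, belonged to a peak on chromosome I at 4769592 to 4769720, in the promoter of rpa-2 (WBGene00019767), which encodes a subunit of replication protein A. The next highest, 294, lay on chromosome III at 3867524 to 3867646, in the promoter of the ribosomal protein gene rpl-3 (WBGene00004414). The peak ranked 3 (signal 281, chromosome V, 12303587 to 12303702) overlapped the small nucleolar RNA gene C51F7.4 and lay within 200 bp of another, C51F7.3, both inside frm-7 (nearest protein-coding start, F55C5.17). Peaks ranked 4 and 5 (signals 270 and 255) were intergenic on chromosome IV, and K08F11.1 had the nearest start of a protein-coding gene to each.

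Of the 25 peaks of highest signal, 10 lay in the promoter of a protein-coding gene and 5 lay within 200 bp of a tRNA, snRNA or snoRNA gene. Promoter peaks in this set were those of rpa-2, rpl-3, tasp-1 with K01G5.10 (signal 216), the ubiquitin ligase gene eel-1 (213), rpl-15 with K11H12.8 (195), rpl-20 with Y17G9B.5 (194), the egg-to-embryo transition gene egg-5 (188, at the SL2 RNA gene sls-2.4), K07C5.3 with K07C5.13 (187), the AAA ATPase gene cdc-48.1 (163) and nspc-17 (159). Peaks inside introns had signals of 233 in the peroxidasin gene pxn-1, 187 in the calmodulin-dependent kinase gene cmk-1 (nearest start, ccm-2), 165 in cutl-18 and 155 in the autophagy gene epg-9. A peak with a signal of 163 lay in coding sequence of the folate transporter gene folt-2. Other exons held a peak with a signal of 186 at the microRNA gene mir-51 (nearest protein-coding start, hrg-5) and one of 184 in the lincRNA gene linc-128. The nearest protein-coding start to the latter, 4741 bp away, was that of the calmodulin gene cmd-1. The remaining intergenic peaks of the set were nearest to the starts of Y116A8A.150 (242), C46C2.7 (214), K07D4.2 (172), the chemoreceptor gene srh-243 (168) and W03C9.1 (165). All 25 positions were also present in the ranked list of each replicate. The 25 included all 8 peaks of the list narrower than 276 bp, those ranked 1 to 5 among them.

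Peaks were more frequent in promoters than at random positions. A promoter, counted from 1000 bp upstream to 200 bp downstream of a protein-coding start, held 293 of the 843 summits, or 34.8% (exact 95% interval 31.5 to 38.1%), against 26.3% of uniformly placed positions, a ratio of 1.32. Exons without coding or UTR annotation held 73 summits (8.66%), 3.02 times the random share. Introns held 141 summits (16.7%), 0.628 times the random share, and intergenic sequence 159 (18.9%), 0.835 times. Coding sequence (161 summits, 19.1%), 3' UTRs (12) and 5' UTRs (4) did not pass the test, although 3' UTRs passed as lower in the authors' other joint list (0.539 times, permutation adjusted p = 0.0333) and stood above random with GC-matched placements (1.74 times, adjusted p = 0.167). Two-sided permutation tests over 10000 placements gave p = 0.0002 for promoters, the smallest they can give, and adjusted p-values over the 7 classes of 0.000467 for promoters, other exons and introns and 0.0175 for intergenic sequence. Permutation placements matched on GC content gave coding sequence a lower share than random, at 0.567 times (adjusted p = 0.000467), lowered the ratio of other exons to 1.93, and ended the calls for introns (0.970 times, adjusted p = 0.722) and intergenic sequence (1.08 times, adjusted p = 0.413). Coding sequence also fell below random in each replicate's own list (0.322 times for replicate 2 and 0.460 times for replicate 1). Without soft-masked summits, but with placements that still took in soft-masked sequence, it passed above random (1.20 times, permutation adjusted p = 0.0199). In the replicates' own lists, intergenic sequence missed the threshold in both (1.21 times, permutation adjusted p = 0.327, and 0.977 times, adjusted p = 1). Other exons stood at 4.84 and 4.52 times in these lists, introns missed the threshold in that of replicate 1 (0.616 times, permutation adjusted p = 0.0850), and other exons missed it without the peaks near tRNA, snRNA or snoRNA genes (1.23 times, permutation adjusted p = 0.375).

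Genes for small noncoding RNA were the features with the largest excess of peaks. Summits within 200 bp of a tRNA gene numbered 58 (6.88%; exact 95% interval 5.27 to 8.80%), 25.4 times the random share of 0.271%. Genes for snRNA had 14 such summits (25.7 times) and genes for snoRNA 38 (24.4 times). The broad annotation class ncRNA had 125 (14.8%, 4.28 times). Near genes for piRNA, the Piwi-bound small RNA of the germline, there were 4 summits (0.474%), 0.158 times the random share. Counted by gene, 67 of 612 tRNA genes (10.9%), 14 of 129 snRNA genes (10.9%) and 38 of 346 snoRNA genes (11.0%) had a summit nearby. No summit lay near any of the 20 rRNA genes (exact upper limit 0.437%). With the 62 peaks past the same IDR limit that the list leaves out added, the rRNA class passed at 12.5 times random (permutation adjusted p = 0.0336). The 3 summits near microRNA genes, 2 near lincRNA genes and 2 near antisense RNA genes did not pass the test. In 2-sided permutation tests each of the 5 classes named first had an adjusted p = 0.000360, from the smallest p that 10000 placements can give, over 9 classes.

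The tRNA genes at the strongest peaks were WBGene00014474 on X (signal 120), WBGene00014446 on I (115) and WBGene00014478 on X (113). Among snRNA genes, the leading members sls-2.4 (188), sls-2.1 (118) and sls-2.9 (115) encode the spliced leader SL2, which is joined to the 5' end of messages from downstream genes of operons. Leading snoRNA genes were C51F7.4 and C51F7.3 (one shared peak, 281) and ZK994.7 in pxn-1 (233). In the ncRNA class they were WBGene00195021 (255), R12E2.18 (188, at the peak of sls-2.4) and F36H1.17 (186, at the peak of mir-51), and in the piRNA class 21ur-11151 (98.8), 21ur-2300 and 21ur-7587 (one shared peak, 73.2). Against GC-matched permutation placements the ratios were lower, at 11.5 for tRNA, 9.44 for snRNA, 10.9 for snoRNA and 2.43 for ncRNA (adjusted p = 0.000450 for each), and the piRNA call was lost (0.465 times, adjusted p = 0.227). Within 500 bp instead of 200 bp the ratios were 12.6 for tRNA, 13.2 for snRNA, 12.9 for snoRNA, 2.63 for ncRNA and 0.320 for piRNA. Away from tRNA, snRNA and snoRNA genes, 68 of 734 summits lay near ncRNA genes, 2.89 times random (permutation adjusted p = 0.000600). In the 99 peaks listed for replicate 2 alone the tRNA ratio was 4.02 (permutation adjusted p = 0.560) and the microRNA class passed (19.7 times, adjusted p = 0.0194), against tRNA at 25.5 times in the 81 peaks listed for replicate 1 (adjusted p = 0.000600); the piRNA call was lost in both (0.278 times, adjusted p = 0.375, and 0 times, adjusted p = 0.139). The snRNA ratio was 89.02 and 36.9 and the snoRNA ratio 44.7 and 60.3 in the lists of replicate 2 and replicate 1. These lists are short and the random shares small, at 0.271% for tRNA and 0.116% for microRNA genes in the main list. The tRNA and microRNA ratios of replicate 2 and the snRNA ratio of replicate 1 therefore rest on very few summits.

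**Figure D1:**
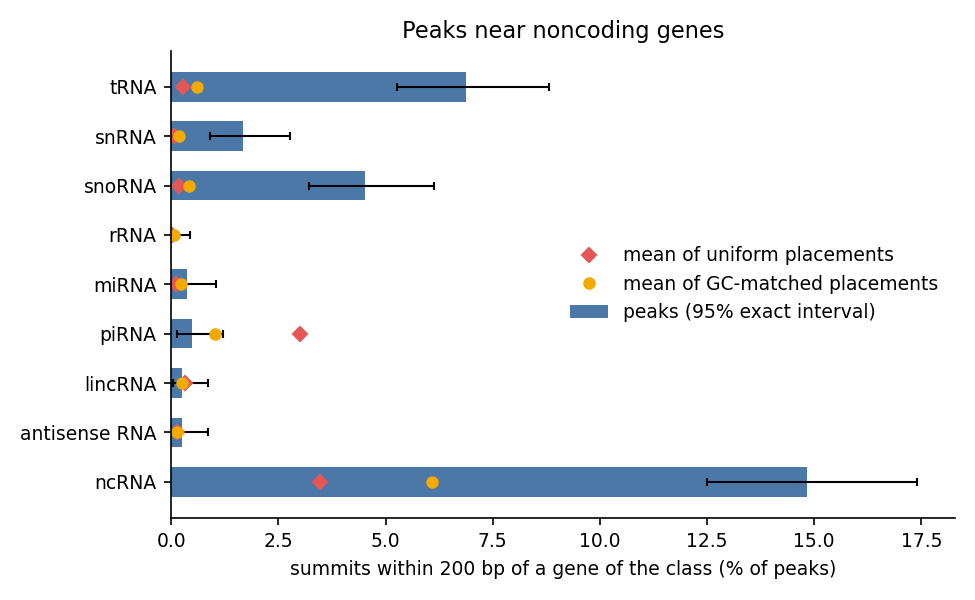
Share of the 843 summits within 200 bp of a gene of each noncoding class, in percent, with exact 95% intervals (bars and lines). Diamonds mark the mean of uniform placements and circles the mean of GC-matched placements; tRNA, snRNA, snoRNA and ncRNA bars lie above both, and piRNA lies below the uniform mean.

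Ribosomal protein, chaperone, translation factor and secretion genes were found at peaks more often than other protein-coding genes. A summit lay in the promoter of 344 of 19973 protein-coding genes (1.72%). Ribosomal protein genes had one in 10 of 81 cases (12.3%, exact 95% interval 6.08 to 21.5%; odds ratio 8.25, adjusted p = 4.35e-05), led by rpl-3 (signal 294), rpl-15 (195), rpl-20 (194) and rpl-35 (146). Chaperone genes had one in 6 of 62 (odds ratio 6.20, adjusted p by Fisher's exact test = 0.0116), with the mitochondrial chaperonin gene hsp-60 (140), the ER chaperone gene hsp-3 (115), dnj-28 (95.4) and the cytosolic chaperonin gene cct-7 (88.3) at the strongest peaks. Translation factor genes had one in 4 of 42 (odds ratio 6.07, Fisher's exact adjusted p = 0.0281), at ifet-1 (108, a peak shared with the ribosomal protein gene rps-1), iff-2 (83.6), eif-3.C (79.3) and eif-4A3 (61.4). Genes of protein secretion and trafficking had one in 8 of 138 (odds ratio 3.57, Fisher's exact adjusted p = 0.0186), among them the translocon genes sec-61.G (103.6) and sec-61.B with trap-3 (one shared peak, 97.1), and vps-39 (95.98). All list tests were 2-sided Fisher's exact tests, adjusted over 34 lists fixed before the data were examined.

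Respiratory chain, histone, germline, other transcription factor and microRNA genes also passed toward higher shares, and chemoreceptor genes passed toward a lower share. Mitochondrial respiratory chain genes had a summit in 4 of 50 cases (odds ratio 5.01, Fisher's exact adjusted p = 0.0404), at the cytochrome oxidase genes cox-5A (108), cox-6A (83.5) and cox-5B (81.6) and the ATP synthase gene atp-4 (67.6). Histone genes had one in 5 of 81 (odds ratio 3.79, Fisher's exact adjusted p = 0.0442), at 4 distinct peaks, with his-37 (129), his-47 (78.8) and his-59 with his-60 (one shared peak, 77.8) leading. Germline and embryo-deposited genes had one in 8 of 160 (odds ratio 3.05, Fisher's exact adjusted p = 0.0282), led by egg-5 (188), the replication clamp gene pcn-1 (120), atx-2 (96.99) and the synaptonemal complex gene syp-4 (90.7). Other transcription factor genes, outside the homeobox and nuclear receptor lists, had one in 8 of 153 (odds ratio 3.20, Fisher's exact adjusted p = 0.0281), led by ztf-7 (86.8), zip-9 (85.2), cebp-1 (73.6) and hlh-30 (70.8). MicroRNA genes, compared with annotated genes of every type, had one in 11 of 260 (odds ratio 2.99, Fisher's exact adjusted p = 0.0186), but 7 of the 11 were the clustered genes mir-35 to mir-41 behind 1 peak (chromosome II, 11537208 to 11537483, signal 86.4). Without that peak, 4 of 260 remained (odds ratio 1.06, Fisher's exact p = 0.793), with mir-51 (186) and mir-80 (89.9) at the strongest. Chemoreceptor genes had one in 10 of 1364 (0.733%, odds ratio 0.404, Fisher's exact adjusted p = 0.0186). Leading were sre-23 (120, within 200 bp of the snoRNA gene ZK265.10), srx-28 (92.6), srj-55 (91.2) and sri-5 (84.4). Of the 10, 2, srj-55 and str-39, lay in the window around F37B4.10.

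The ribosomal protein call was kept under all 14 alternatives run, and each of the other 9 calls was lost under 3 to 9 of its alternatives. Alternatives in which a list had no member at a peak are not in these counts. Without the peaks near tRNA, snRNA or snoRNA genes, which include those of egg-5, syp-4 and cox-6A, the germline (2.56, Fisher's exact adjusted p = 0.121) and respiratory chain calls (4.18, adjusted p = 0.124) were lost. In the authors' other joint list the translation factor (4.04, Fisher's exact adjusted p = 0.136), respiratory chain (3.35, adjusted p = 0.191) and histone calls (3.47, adjusted p = 0.0688) were lost. In the list of replicate 1 alone, ribosomal protein genes (odds ratio 26.4, Fisher's exact adjusted p = 0.000467), histone genes (19.1, adjusted p = 0.00800) and microRNA genes (17.8, adjusted p = 1.56e-06) passed. Genes sharing a peak were counted separately there, as were the clustered microRNA genes in the main list. Counted by summits within 200 bp, the microRNA class did not pass in the same list (10.6 times, permutation adjusted p = 0.272). In that of replicate 2, ribosomal protein genes alone passed (46.9, Fisher's exact adjusted p = 2.6e-08), while histones (5.39, adjusted p = 0.740), microRNA genes (3.68, adjusted p = 0.540), the respiratory chain (8.82, adjusted p = 0.540), chaperones (14.7, adjusted p = 0.0796) and germline genes (8.59, adjusted p = 0.0716) did not. In replicate 1, chaperones (7.76, Fisher's exact adjusted p = 0.710), germline genes (6.10, adjusted p = 0.395) and chemoreceptors (0.324, adjusted p = 1) did not pass, and secretion, translation factor and other transcription factor genes had no member in either list. Against GC-matched permutation placements, ribosomal protein genes (7.27 times, adjusted p = 0.0165), chaperones (7.40 times, adjusted p = 0.0165) and secretion genes (4.07 times, adjusted p = 0.0330) passed. Germline (3.40 times, permutation adjusted p = 0.0660), other transcription factor (2.83 times, adjusted p = 0.0726), translation factor (5.76 times, adjusted p = 0.0935), respiratory chain (4.95 times, adjusted p = 0.0990) and histone genes (1.59 times, adjusted p = 0.987) missed the threshold there, and chemoreceptor genes came out at 1.09 times random. The whole peak set was also shifted along the chromosomes, which keeps neighbouring genes together. Histones (5 genes against a mean of 0.805 by shift, permutation adjusted p = 0.0733) and chemoreceptors (10 against 14.2, adjusted p = 0.747) were lost there. The other 7 called protein-coding lists passed.

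None of the other lists passed with the main settings. Chromatin regulators had 6 of 143 genes at peaks (odds ratio 2.53, Fisher's exact p = 0.0376, adjusted p = 0.116), among them set-16 (145), the CBP/p300 homologue cbp-1 (122), lin-9 (107) and set-21 (107, a peak shared with the ribosomal protein gene rpl-7A), and passed in the authors' other joint list (odds ratio 4.46, Fisher's exact adjusted p = 0.00142). Nuclear hormone receptors had 6 of 274 (nhr-141 at 122, nhr-40, nhr-66 and nhr-255), pharynx markers 4 of 92 (pqn-71 at 100.1, pqn-36, phat-3 and myo-5), cuticle genes 4 of 226 (col-111 at 92.8, col-72, col-142 and ptr-1; by nearest start they passed, odds ratio 2.25, Fisher's exact adjusted p = 0.0265) and F-box genes 4 of 322 (fbxa-133 at 79.0, fbxa-74, fbxa-76 and fbxb-72). Autophagy and lysosome genes had 3 of 54 (atg-9 at 83.9, hlh-30 and lgg-2) and C-type lectins 3 of 240 (clec-57 at 82.9, clec-127 and clec-126). The peaks of pqn-71, nhr-255, clec-57 and clec-126 also lay within 200 bp of a tRNA or snRNA gene. Counts were 2 for glycolysis and central carbon metabolism (of 48), detoxification enzymes (of 224), intestine markers (of 81) and ion channels and neurotransmitter receptors (of 179). They were 1 for vitellogenins (of 6), neuronal markers (of 41), neuropeptides and insulins (of 144), RNA splicing and processing (of 56), innate immune effectors (of 128) and lipid metabolism (of 109). Homeobox genes (91), hypodermis markers (68), major sperm proteins (56), body-wall muscle markers (50), the proteasome (33), aminoacyl-tRNA synthetases (32) and the vacuolar ATPase (20) had none. Fisher's exact adjusted p for these lists lay between 0.116 and 1.

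**Figure D2:**
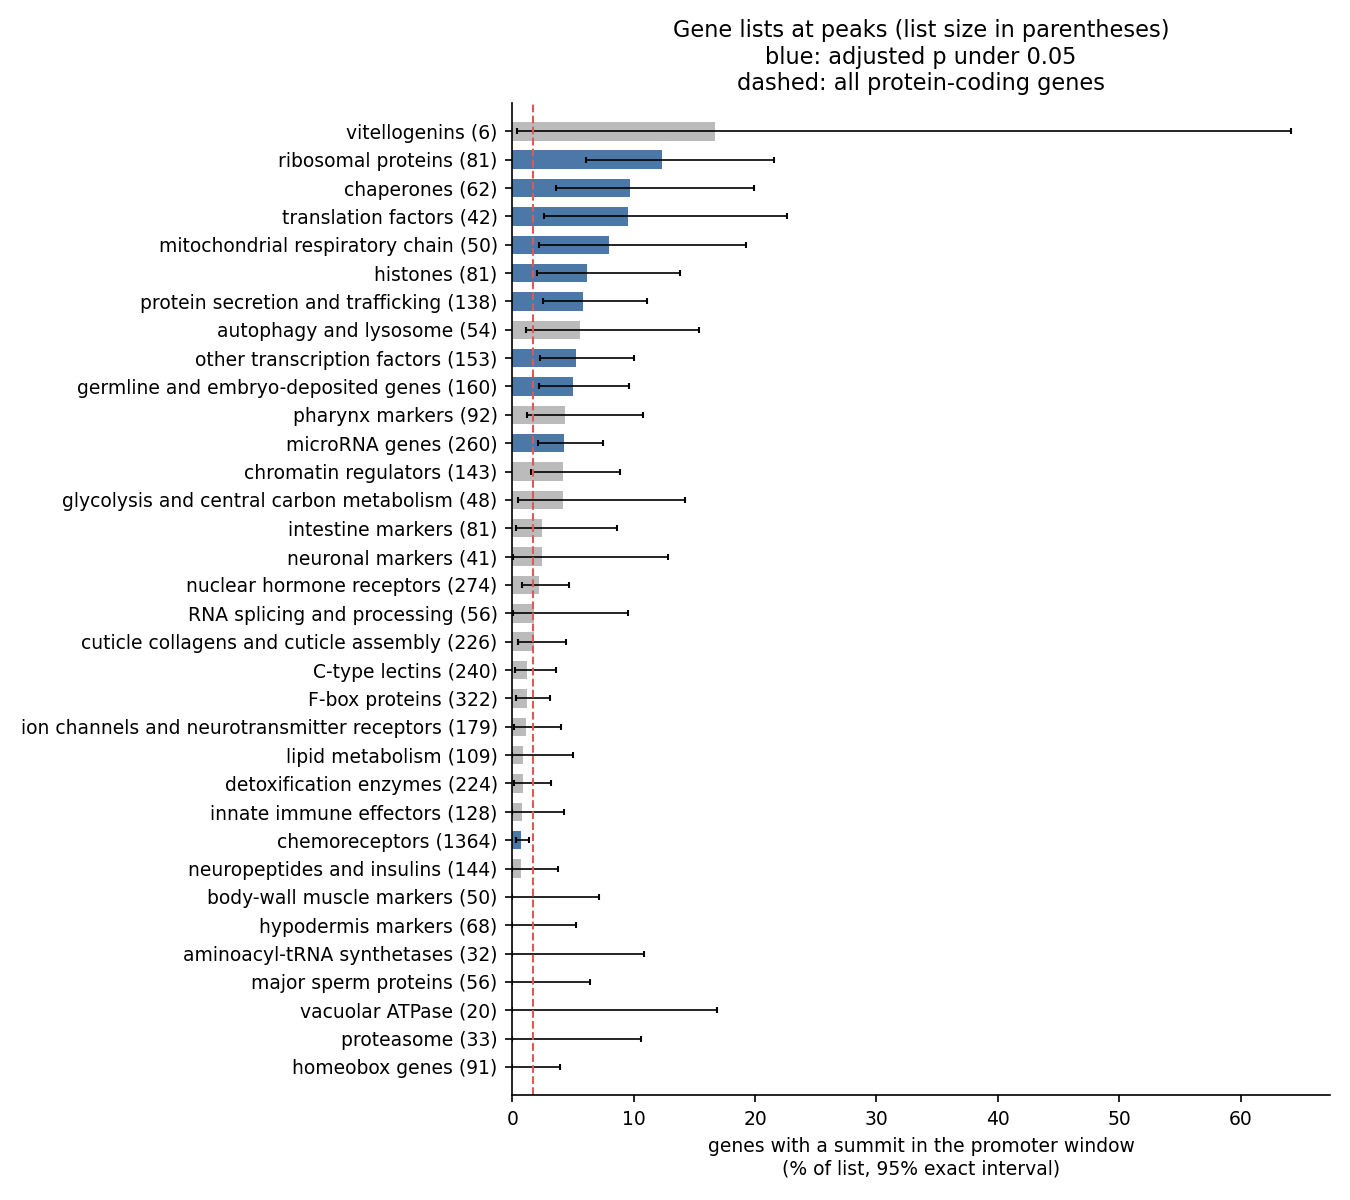
Share of each gene list's members with a summit in the promoter window, in percent, with exact 95% intervals (bars and lines, list size in parentheses). Blue bars passed Fisher's exact test after adjustment over 34 lists, grey bars did not, and the dashed line marks the 1.72% of all protein-coding genes; ribosomal proteins stand at 12.3% and chemoreceptors at 0.733%.

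The region around F37B4.10 itself, the gene carried by the transgene, held a cluster of peaks. Within 20000 bp of the gene (WBGene00018140, chromosome V, 2875734 to 2877609, minus strand) there were 14 peaks, against a mean of 0.349 in random windows of the same size (one-sided permutation p = 0.0002). Of 10000 random windows 1 held as many peaks, with 16, and it overlapped the window of F37B4.10 itself. Of the 14, 13 lay within 13609 bp, from the summit at 2871471 to that at 2885080. They covered srh-243, folt-2, F37B4.10, str-39, the intermediate filament gene ifc-1 and sre-24, with 6 of the 14 summits in coding sequence, 5 in promoters, 2 in introns and 1 between genes. The median signal was 94.7, against 75.1 for all other listed peaks, and the highest was 168, at rank 19 of the list. A peak of signal 37.7, ranked 826 of 843, lay in the promoter of F37B4.10 but was found in neither replicate's own ranked list. One of signal 135 lay in the gene's coding sequence. Another, of signal 94.7, lay inside F37B4.10 and in the promoter of folt-2. The lists of replicate 1 and replicate 2 alone had 6 peaks each in the window. No peak lay within 20000 bp of unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935), the marker gene that the transgene also carries, where random windows held a mean of 0.384 (one-sided permutation p = 1).

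**Figure D3:**
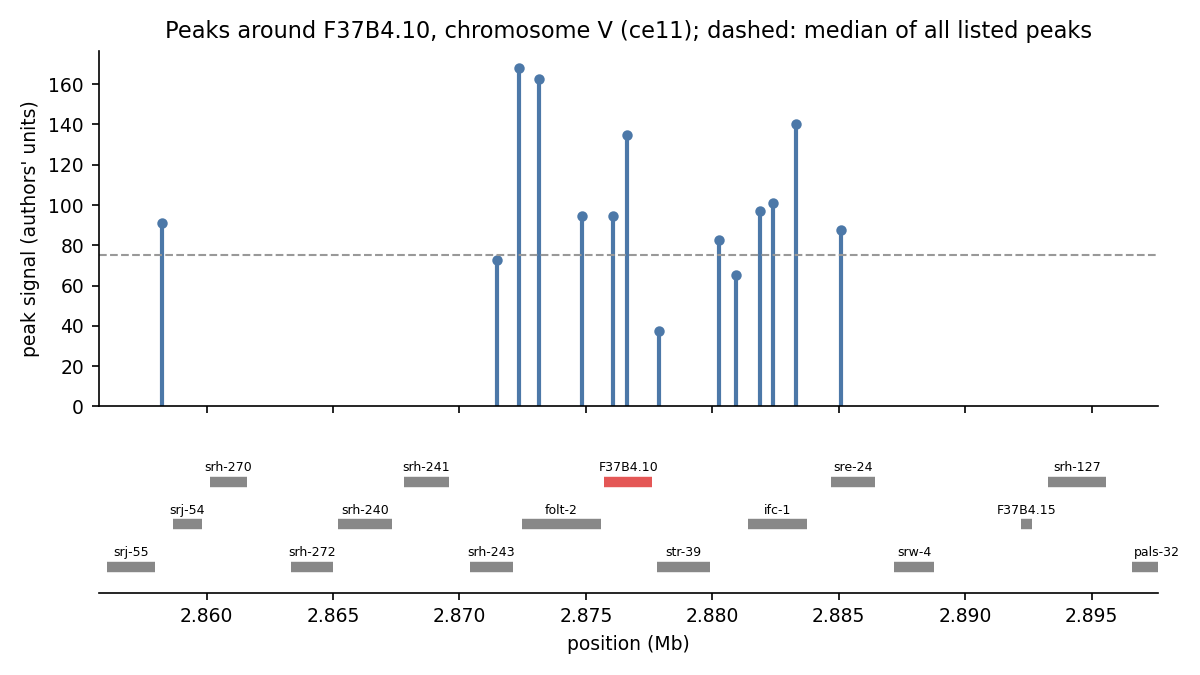
Signal in the authors' units (y axis) of the 14 peaks around F37B4.10 at their summits on chromosome V in Mb (x axis), above the annotated protein-coding genes, with F37B4.10 in red. The dashed line is the median of all listed peaks, 75.3, and 11 of the 14 summits rise above it.

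DNA at the summits was rich in G and C. The median GC content within 50 bp of a summit was 50.5%, against 34.7% for all windows of that size in the genome. Of 2080 sequences of 6 bases, counted on both strands together, 918 differed from flanking windows centred 300 bp away by 2-sided Fisher's exact test with Benjamini-Hochberg adjustment. The 585 found more often at summits held 4.21 G or C bases on average, and the 333 found less often held 1.26. The 10 of smallest p were all less frequent at summits: AAAAAT (17.8% of peaks against 45.02% of flanks, odds ratio 0.264, Fisher's exact adjusted p = 1.81e-40), AAAAAA (14.1 against 39.1%), TAAAAA (7.71 against 29.8%), AAAATT (15.5 against 40.5%), AAAATA (7.12 against 28.1%), TGAAAA (12.2 against 33.7%), TTAAAA (6.29 against 24.4%), GAAAAA (17.4 against 37.1%), ATTTTC (12.7 against 30.5%) and ATAAAA (6.29 against 21.1%).

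Of 26 known factor sites fixed before the data were examined, 9 differed from flanks. More frequent at summits were the SP1/KLF site GGGCGG (7.59% against 2.02%, odds ratio 3.99, Fisher's exact adjusted p = 6.2e-10), CTGCGTCTC (3.20% against 0.652%, odds ratio 5.04), GAGAGA (11.4% against 6.58%, odds ratio 1.82) and CCACCC (4.03% against 2.25%, odds ratio 1.82). Less frequent were TTTGAA (odds ratio 0.374), the TATA box TATAAA (0.301), the homeodomain core TAATTA (0.117), the GATA site TGATAA (0.481) and the SOX core ACAAAG (0.587). None of these 5 passed against random windows matched on GC content, where the odds ratio turned above 1 for TATAAA (1.52), TGATAA (1.22) and TTTGAA (1.08), as it did against shuffled sequence (1.96, 1.82 and 1.22), and for CCACCC it turned below 1 (0.929 and 0.782). Against random windows matched on GC content, 21 of the 6-base sequences were called, led by ACGCAG (9.73% against 4.57%, odds ratio 2.25, Fisher's exact adjusted p = 0.00274), and 13 against dinucleotide-shuffled sequence. Of the 9 sites, CTGCGTCTC alone passed with the GC-matched windows (odds ratio 2.20, Fisher's exact adjusted p = 0.0470), and it alone passed with shuffled sequence (odds ratio 27.9, adjusted p = 4.62e-06). With the GC-matched windows, 3 others passed, the heat shock unit TTCTAGAA (1.07% against 0.119%, odds ratio 9.09, Fisher's exact adjusted p = 0.0174) as more frequent and CACCTG (odds ratio 0.428) and CAGCTG (0.539) as less frequent, against odds ratios of 1.21 and 1.24 with flanks. None of these 3 passed with shuffled sequence (odds ratios 9.09, 0.744 and 1.51, Fisher's exact adjusted p = 0.137, 0.555 and 0.431). In the lists of single replicates, 69 and 79 of the 6-base sequences and 1 and 2 of the sites passed.

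Peaks were spread over the chromosomes in proportion to their length. Shares ranged from 14.4% on chromosome I (121 peaks) to 21.6% on V (182), with adjusted p by exact binomial test of 0.564 or more for each of the 6 chromosomes. The central 50% of the autosomes held 337 of 703 autosomal peaks (47.9%, exact 2-sided binomial p = 0.291). Of the promoter peaks, 54 of 293 (18.4%) lay on chromosome III, which has 13.2% of protein-coding genes. The difference did not pass correction over chromosomes (exact binomial p = 0.0120, adjusted p = 0.0722). The authors' other joint list, the list of replicate 2 and the main list without the peaks near tRNA, snRNA or snoRNA genes each gave 1 chromosome past the threshold, and the list of replicate 1 gave 0.

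Promoter peaks were slightly stronger than the rest, with a median signal of 77.1 against 74.8 for the 550 other peaks (difference 2.33, 2-sided permutation p = 0.0170). It missed the threshold with the 62 unlisted peaks past the IDR limit added (1.81, permutation p = 0.127), among the 421 peaks of highest signal (3.13, permutation p = 0.0677), in the lists of replicate 2 (5.61, p = 0.231) and replicate 1 (2.10, p = 0.783), and with a promoter from 2000 bp upstream to 500 bp downstream (1.504, p = 0.0855). With a promoter from 500 bp upstream to 100 bp downstream it was 4.33 (permutation p = 0.0003).

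The replicates shared far more peak positions than chance placement gives. Of the 81 peaks listed for replicate 1, 46 (56.8%, exact 95% interval 45.3 to 67.8%) overlapped one of the 99 listed for replicate 2, against 0.0376 at random placement (one-sided permutation p = 1e-04, the smallest 10000 placements can give). From the other side, 47 of 99 overlapped (47.5%, 37.3 to 57.8%). The joint list was made from both replicates, so its overlap with each is partly built in: its 843 peaks took in 76 of the 81 peaks of replicate 1 (93.8%) and 90 of the 99 of replicate 2 (90.9%).

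Signal was compared between replicates across peaks already selected for reproducibility. Across the 843 peaks the signals of the 2 inputs of the joint list had a Pearson r of 0.638 and a Spearman rho of 0.0124, a description across peaks, which are not independent replicates. With the 25 peaks of highest signal removed, those of rpa-2, rpl-3 and the frm-7 snoRNA genes among them, which narrows the range of the same measure, r was 0.259 and rho −0.0797. Over all 115634 ranked peaks r was 0.416 and rho 0.280. Both replicates' own ranked lists held 764 of the 843 peaks, and the signal was higher in replicate 2 at 537 of these, with a median ratio of 1.16 that holds only if both lists use 1 scale.

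**Figure D4:**
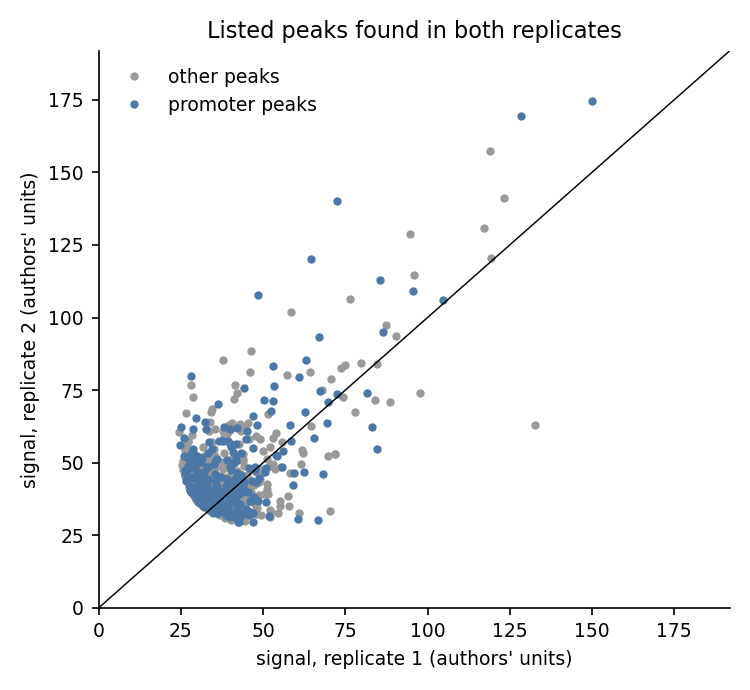
Signal of the 764 peaks found in both replicates' own ranked lists, in the authors' units, for replicate 1 (x axis) and replicate 2 (y axis), with promoter peaks in blue, other peaks in grey and a line of equal signal. Most of the strongest peaks lie on or above the line, and most of the rest form one cloud, with medians of 35.6 and 41.5 for the 2 replicates.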

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

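The comparisons in this part were chosen after the lists had been seen. The joint ranked list holds 905 peaks past the IDR limit of 0.01, and 62 of them are absent from the conservative list of 843, which drew attention because some outrank every listed peak in signal. Their median signal was 127, against 75.3 for the listed peaks, and 4 exceeded the highest listed signal of 321. The strongest lay in intergenic sequence on X at 15810973 to 15811248 (signal 1494), followed by peaks starting at 10947419 on I (421), 5284686 on V (396) and 9047360 on IV (338). Of the 62, 51 summits (82.3%, exact 95% interval 70.5 to 90.8%) were soft-masked as repeats or low complexity in the reference, against 164 of 843 listed summits (19.5%, 16.8 to 22.3%; odds ratio 19.2, 2-sided Fisher's exact p = 4.87e-24). None lay in a promoter, 55 were intergenic, and 2 lay within 200 bp of the 5S ribosomal RNA gene rrn-4.2 on V. The replicates' own lists left out peaks past the limit too, 35 for replicate 1 and 37 for replicate 2. Per the README files, the thresholded lists were derived from 1 further file that the ranked lists were not, and its content was not analysed here.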

How the results depend on the processing

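Results without soft-masked summits, without peaks near small RNA genes, without the 25 strongest peaks, with the 62 unlisted peaks, with 1 flank per peak, or with GC-matched controls were chosen after seeing the data. Of the main results under their alternatives, 80 were classed as the same, 24 as weaker, 3 as passing newly and 3 as moved. Most of these results are counts of calls, and a count classed as the same could still change. Called gene lists went from 10 to 8 in the other joint list. Among the 421 strongest peaks, 6-base sequences went from 918 to 677 and sites from 9 to 7. For single lists and classes, 406 stayed on their side of the threshold. Of these, 39, past no threshold either way, lay on the other side of no difference. A further 61 were weaker, 5 passed newly and 8 turned with a call involved. A list with no member at a peak in a setting was left out of these counts, so calls lost in that way are not among them. The promoter share stayed past the threshold throughout (37.4 to 39.5% in the lists of single replicates). Those lists hold 81 and 99 peaks, so their tests have less power. They gave 0 to 1 chromosome for promoter peaks, 1 to 3 gene lists, 69 to 79 sequences of 6 bases, 1 to 2 sites, signal differences of 2.10 to 5.61 and 6 to 6 peaks at F37B4.10. Against 10 called gene lists, there were 4 among the 421 strongest peaks, 3 and 5 with the narrower and wider promoter, 4 by nearest gene (1 of them, cuticle genes, newly), 3 among genes with a symbol and 3 with GC-matched placements; the microRNA list was not run by shift, GC-matched, nearest gene or symbol. Chromosomes called for promoter peaks rose from 0 to 1 with the other joint list and to 1 without peaks near small RNA genes, which left 2 genomic classes. Sequences of 6 bases called fell from 918 to 432 in promoter peaks alone, 21 with GC-matched and 13 with shuffled controls, and sites from 9 to 4 with GC-matched windows. The signal difference of 2.33 was 3.13 among the strongest peaks, 1.504 with the wider promoter and 1.81 with the unlisted peaks, past no threshold in any of these, and 4.33 with the narrower promoter (permutation p = 0.0003). Pearson's r of 0.638 was 0.416 over all ranked peaks, 0.438 on the log2 scale and 0.259 without the 25 strongest, which narrows the range of signal. Besides the sites TATAAA, TGATAA, TTTGAA, CCACCC, CACCTG and CAGCTG (other controls), turned ratios with a call on either side were coding sequence, from 1.01 to 0.322 and 0.460 in single replicates and 0.567 with GC-matched placements; intergenic sequence, from 0.835 to 1.21 in the list of replicate 2 (0.977, not turned, in that of replicate 1), 1.05 with the unlisted peaks and 1.08 with GC-matched placements; rRNA genes, from 0 to 12.5 (adjusted p by permutation 0.0336) with the unlisted peaks, 2 of which lie at rrn-4.2; and chemoreceptors, from 0.404 to 1.09 with GC-matched placements. The cause was not tested. The tRNA, snRNA and snoRNA classes without peaks near their own genes, and transgene loci without themselves, were not run, being empty by construction. No paired comparison of groups was possible because the design has 1 group. The pairing of each summit with its own flanks was not used in the sequence tests.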

Other observations

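The tests in this part were chosen only after the result was seen, except those on all 337 genes without shared sequence and on F37B4.10 peaks outside the lists. Genes for tRNA, snRNA and snoRNA were concentrated at the top of the joint ranked list. Within 200 bp of such a gene lay 11.3% of the 1000 strongest-ranked positions, 3.83% of ranks 1001 to 5000, 1.35% of ranks 5001 to 20000 and 0.412% of ranks 60001 to 115634, while the median GC content of the same bins went from 49.5% to 36.6%. Promoter shares changed little over the same ranks, from 29.6% to 26.4%. Among the 843 listed peaks, the 109 near these genes had a median signal of 82.7 against 74.8 for the rest (difference 7.86, 2-sided permutation p = 2e-05, the smallest 100000 permutations can give).

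Genes for tRNA on chromosome II were at peaks more often than those elsewhere, 13 of 57 (22.8%, exact 95% interval 12.7 to 35.8%, odds ratio 2.74, Fisher's exact adjusted p = 0.0363 over 6 chromosomes). Genes sharing a peak were counted separately, on chromosome II WBGene00023164 with WBGene00023165 and WBGene00023161 with WBGene00023162. On X, which holds 276 of the 612 tRNA genes, 35 were at peaks (12.7%, Fisher's exact adjusted p = 0.380). Of the 18 sls-2 genes, which encode the SL2 spliced leader, 4 were near a peak, against 10 of 111 other snRNA genes, a difference that did not pass (Fisher's exact p = 0.108). Of the joint peaks, 651 of 843 (77.2%) were overlapped by the authors' other joint list, with a median signal of 78.6 against 67.4 for the 192 that were not.

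Peaks near tRNA, snRNA and snoRNA genes could come from the GC content of these genes or from reads shared between their near-identical copies. Against placements matched on GC content the lowest of the 3 ratios was 9.44, for snRNA, which argues against GC content as the whole source, although matching lowered the ratios from 24.4 or more. The 337 genes that share no 30-base sequence with the rest of the genome had 37 peaks nearby, 24.9 times random (permutation p = 0.0002, the smallest possible), and the 40 tRNA and snRNA genes among them had 4, or 24.1 times (permutation p = 0.0002), which argues against shared reads as the whole source. Enrichment of highly transcribed chromatin in any pull-down stays open, since the control library was not analysed here, and binding by F37B4.10 was not tested against it.

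The cluster of 14 peaks at F37B4.10 may come from extra copies of the clone in the transgene, or from binding there. All 54 ranked peaks of the window had a median signal of 42.98, above the 28.5 that 95% of random windows stayed under, but they include the listed peaks that make up the cluster, so this restates it and decides nothing. The 37 ranked peaks in neither thresholded list had a median of 26.5, under the 28.2 of that bound; this was set beforehand to count against extra copies, but wrongly, since leaving out the listed peaks removes those that copies would raise. The window of unc-119, a gene also on the transgene, had a median of 25.4, higher than 74.7% of random windows. How much of that window the transgene carries is not given, so the value decides nothing about extra copies. Binding and copy number cannot be told apart here, because both raise the signal and the extent of the clone is not given in the sources used here.

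The many GC-rich 6-base sequences at summits may follow from base content. Against flanks 918 were called, against GC-matched windows 21 (19 of them among the 918) and against dinucleotide-shuffled sequence 13 (8 among the 918 in the same direction), far fewer, as base content would give. Shuffled sequence gave 1 control per peak, and with 1 flank per peak 693 and 739 were called. ACGCAG led with GC-matched windows and missed the threshold with shuffled sequence (Fisher's exact adjusted p = 0.0782). AGACGC alone passed with both controls (odds ratios 1.93 and 2.16, Fisher's exact adjusted p = 0.0271 and 0.0459). Both sequences, read on either strand, are part of the site CTGCGTCTC, which also passed with both controls. No biological explanation was tested, since the design has 1 group.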
